A study of Mus musculus with 6 samples.

How the data were processed

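The data were single-cell RNA sequencing of sorted germinal centre (GC) B cells from mouse spleen after immunisation with NP-haptenated antigen in alum, in 6 libraries made with 5-prime droplet chemistry. Samples were grouped by the labels into Day7 (2 libraries), Day14 (2 libraries), Chimaera_control (1 library) and Chimaera_KO (1 library). The labels do not say that replicates came from separate animals, so spread between replicates measures only how these libraries differ.

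The deposited tables hold UMI counts per gene and cell, which the authors left unnormalised. The submitters name Cell Ranger, Seurat and the mm10 genome, without versions or settings. The values were checked as whole numbers with totals that differ between cells. The deposited cell tables add a library label, a cell cycle phase, a zone call (LZ, DZ or unknown) and a cluster number for each cell. How those calls were made is not stated. The 1 other column, of barcode names from receptor sequencing, was not used.

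The 3 tables differ in construction. The Day7 table lists 27998 gene symbols and no immunoglobulin genes, and its cells hold 7290 to 49966 UMIs with at most 4.99% mitochondrial counts. The Day14 table lists 31053 symbols, and its cells hold 500 to 9998 UMIs with at most 19.99% mitochondrial counts. The Chimaera table lists 15763 symbols, and its cells hold 554 to 19996 UMIs with at most 9.97% mitochondrial counts. All deposited cells were kept. Scrublet's automatic threshold called at most 0.296% of the cells of a library, so doublets were instead handled in an alternative that removed the 5% of cells with the highest scores.

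Before the data were examined, the comparisons, their tests, 26 gene lists, cell type markers, the rule for named genes and most alternatives were fixed. The lists cover light zone activation, dark zone, S phase, G2/M, memory-associated, plasma cell, naive follicular, IL-4/STAT6 response, GC identity, MYC-driven growth, CD40/NF-kB, immediate early, interferon, MHC class II, apoptosis, glycolysis, nuclear-encoded oxidative phosphorylation (OXPHOS), trafficking receptors, cytokine receptors, immunoglobulin constant genes, chaperones, T cell, myeloid, stromal, erythroid and sex-linked genes. Named genes were the 12 with the largest difference in each direction among those meeting the criteria of a comparison, without immunoglobulin, mitochondrial, ribosomal and predicted genes, plus 2 to 4 members of each list. Il4ra, Bcl6, Cd38 and Jchain were named beyond this rule, after their values were seen, and any other such gene is marked where it stands. Some list members are not reported by name.

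Deposited clusters were named by the fixed markers. A cluster took the class with the highest median log2 ratio over the other cells of its table, provided that the median reached 0.5, at least 3 markers were raised and no other class led its 10 leading genes. Such names carry "-like". Clusters led by genes of a non-B class that kept B cell transcripts were left unnamed, as were those with no class.

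For KO against control, with 1 library per group, no test was possible. Counts were summed over the cells of a library and divided by the library total (scaled as CPM). Log2 ratios carry exact 95% conditional binomial intervals, and shares of cells or counts carry exact Clopper-Pearson 95% intervals. All such intervals cover counting error only. A gene was past the size rule with a CPM of at least 20 in either library, an absolute log2 ratio of at least 0.5, an interval excluding equality, and a ratio larger than that of the same gene between the 2 Day14 libraries. Lists were described over members with a CPM of at least 5 by their median and its percentile among 10000 random lists of the same size, drawn from the 200 genes nearest to each member in expression. The random range runs from the 2.5 to the 97.5 percentile. On simulated counts with 100 genes changed by a log2 of 1 and 100 by a log2 of 2, the size rule recovered 100% with 0 false calls. Those counts held Poisson counting error only, with no spread between libraries. They therefore cannot show how often the rule passes genes through such spread. Between the real Day14 libraries, 19 non-immunoglobulin genes met the first 3 criteria.

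Day 14 against day 7 used summed counts of symbols listed in both tables, with TMM scaling, filterByExpr and quasi-likelihood tests in edgeR 4.0.16 (R 4.3.3), at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are model estimates, and group means are CPM with the SD over 2 libraries. Standard errors (SE) were derived from the test, as the absolute log2 change divided by the square root of its F statistic. Lists were tested with camera in limma 3.58.1, at a preset correlation of 0.01, and alternatively with an estimated correlation and with fry. On simulated counts, 100% of changed genes were recovered at both sizes, with 6 false calls among 11925 genes. Changed genes were drawn from well-counted ones, and every gene had the same dispersion (0.0068). The simulated days did not differ in annotation, cell depth or cell filters. They therefore cannot show how many real calls follow such differences. With 2 libraries against 2, an exact permutation test of a single value cannot give a p below 0.333.

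Memory-precursor-like cells were compared with the other GC B cells of the same library, plasma-like cells left out, as the mean log2 CPM of a list after adding 1 CPM and without the naming markers. The test was a two-sided exact sign-flip permutation over 4 libraries, whose smallest p is 0.125. The class could not be named at day 7, so the planned 6 libraries became 4.

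Isotype use was the share of heavy-chain constant UMIs taken by each gene, and lambda use was the share of light-chain constant UMIs. Transcript lengths, positions and exon overlaps came from GENCODE M21 on GRCm38. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, matplotlib 3.10.9 and DESeq2 1.42.0. Alternatives covered scaling, filters, thresholds, doublets, cell depth, clustering, cluster shares, a replicate block, leaving out each library and adding the chimaera control to day 14. After the data were seen, further alternatives were added: a shared mitochondrial limit, a shared UMI window, removal of the transcript length trend, clustering without the genes that differ between the chimaera libraries, the list tests with the control added, day shares in cells above the median UMI count, and the memory lists without naive follicular genes, with thinning and list shares taken apart, and with cells weighted alike.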

Results

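GC B cells sorted from mouse spleen were profiled by single-cell RNA sequencing in 6 libraries after immunisation with NP-haptenated antigen in alum. At day 7, 2 libraries of B220+ CD38- GL7hi cells were made, and at day 14, 2 libraries of B220+ CD95hi GL7hi IgD- cells. A further pair came from day 14 of irradiated mice rebuilt with wild-type marrow and sorted with the day 14 gate. The control hosts were Il4ra+/+, and the KO hosts carried Ccl19-Cre with floxed Il4ra, which removes the IL-4 receptor alpha chain from Ccl19-expressing stromal cells, the lineage that includes follicular dendritic cells. Day 7 gave 1012 and 2530 cells with 20339933 and 54010682 UMIs. Day 14 gave 9109 and 10648 cells with 35637133 and 39839045 UMIs. The chimaeras gave 8038 control cells with 62202828 UMIs and 7314 KO cells with 59690886 UMIs. Median UMIs per cell were 17277.5 and 18233.5 at day 7, 3399 and 3178.5 at day 14, 6676 in the control and 7185.5 in the KO library.

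The chimaeras asked how GC B cells differ when host stroma lacks the IL-4 receptor. Il4ra itself (chromosome 7, 125552120 to 125579474) was measured in donor B cells and so does not check the host genotype. It stood at 54.0 CPM in the control and 63.1 CPM in the KO library, a log2 ratio of 0.22 with an interval of 0.16 to 0.29. Of the 14 measured genes of the IL-4/STAT6 response list, 11 had a ratio above 1, and 3 of them were past the size rule. Fcer2a, which encodes the low-affinity IgE receptor CD23, was at 107 CPM in the control and 189 CPM in the KO library (log2 0.83, interval 0.78 to 0.87). Socs1, a feedback inhibitor of cytokine signalling, was at 44.5 and 68.9 CPM (log2 0.63, interval 0.56 to 0.70). Il4i1, an amino acid oxidase induced by IL-4, was at 131 and 188 CPM (log2 0.52, interval 0.48 to 0.57). Bcl6, the GC master regulator, was at 39.95 and 36.4 CPM (log2 -0.13). The list median of 0.06 stood at percentile 94.0 of matched random lists, inside their range, while the mean was 0.27. It lay above the range with equal cluster shares (0.08, percentile 99.8) and with cells weighted alike (0.08, percentile 98.4).

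Across 5189 genes at 20 CPM or more, 35 non-immunoglobulin genes were past the size rule with a higher value in the KO library and 37 with a lower one, as were 6 and 64 immunoglobulin genes. Before the comparison with the day 14 pair, 35 and 45 non-immunoglobulin genes met the first criteria, against 19 between the 2 Day14 libraries. Of immunoglobulin genes, 32 met the first criteria between the 2 Day14 libraries. With equal cluster shares, 17 higher and 50 lower immunoglobulin genes were past the size rule in the chimaeras. Rflnb (chromosome 11, 76019194 to 76027782) had the largest ratio, 4.68 CPM in the control and 25.4 CPM in the KO library (log2 2.44, interval 2.26 to 2.63). Gadd45g, a stress-response gene, followed at 6.88 and 30.7 CPM (log2 2.16), then Serpinb6b at 10.4 and 38.4 CPM (log2 1.88) and Samsn1, an adaptor that restrains B cell activation, at 44.2 and 114 CPM (log2 1.37). Tmem123 (1.18), Pkib (1.16), Wdfy2 (1.12), Dexi (1.08), Rab35 (1.07), Klhdc2 (0.99), Dock10 (0.92) and Slc15a3 (0.85) completed the 12 on the log2 scale. Between the Day14 libraries these 12 genes had log2 ratios from -0.99 for Rflnb to -0.01 for Rab35.

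On the lower side, S100a10 (chromosome 3, 93555080 to 93564643) stood at 99.9 CPM in the control and 34.2 CPM in the KO library (log2 -1.55, interval -1.62 to -1.47), while its log2 ratio between the Day14 libraries was -1.02. Clec2i stood at -1.21, Ccnd2, a G1 cyclin, at -1.11, and Ms4a4c at -1.05. Apoe was at 542 and 302 CPM (log2 -0.84). Slpi, abundant in plasma cells, was at 580 and 295 CPM (log2 -0.98), and at -0.42 once the clusters were given equal shares in both libraries. Pml (-0.98), Itgb7 (-0.97), Sub1 (-0.87, and -0.46 with equal cluster shares), Cmah (-0.80), Ms4a6c (-0.77) and Rpia (-0.75) completed the 12. With 1 library per group, no value here separates host genotype from any other difference between 2 libraries. Requiring a log2 ratio of 1 left 9 and 4 genes, a minimum of 5 CPM gave 55 and 128, and equal cluster shares left 30 and 24.

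**Figure D1:**
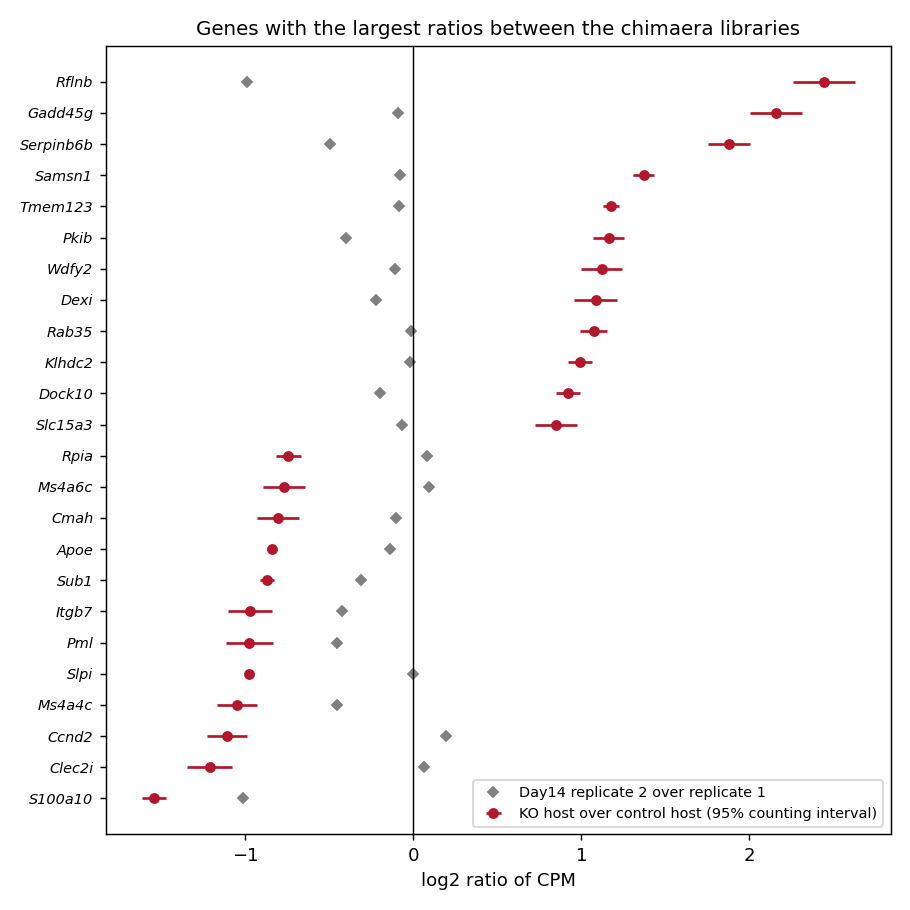
Log2 ratio of CPM (x axis) for the 24 named genes (y axis), KO over control library with 95% counting intervals, and the ratio between the 2 Day14 libraries as grey diamonds. Rflnb reached 2.44 and S100a10 stood at -1.55, where the Day14 pair stood at -0.99 and -1.02.

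Memory-associated genes had lower values in the KO library. Of 17 measured memory-associated genes, 16 had a ratio below 1, with a median log2 of -0.30 at percentile 0 of the random lists, and the Day14 pair had a median of -0.33. With equal cluster shares these were -0.26 and -0.05. Cd38 (-0.74) and Itgb7 (-0.97) were past the size rule, as was the EBI2 receptor gene Gpr183 in the other direction (0.57). Hhex, a transcription factor of memory B cells, stood at -0.99 and at -0.87 in the Day14 pair. The 8 naive follicular genes, 5 below 1 and 3 above, had a median of -0.45 against -0.64 in the Day14 pair, with Ccr7 at -1.93 (Day14 pair -1.60) and Fcer2a alone past the rule, upward. The 13 trafficking receptors had a median of -0.29, against -0.37 in the Day14 pair. With equal cluster shares the naive medians were -0.43 and -0.31 and the trafficking medians -0.21 and -0.04.

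The plasma cell list was lower by a median log2 of -0.34 over 12 genes, 11 of them below 1, against 0.00 in the Day14 pair. With equal cluster shares the median was -0.12. Jchain, the joining chain of polymeric antibody, stood at -0.68 and Fkbp11 at -1.16, while Xbp1 stood at 0.05. With equal cluster shares these were -0.30, -0.35 and 0.28. All 8 measured interferon genes were below 1 (median -0.42, percentile 0, Day14 pair -0.11), with Isg15 at -0.60 and Ifi203 at -0.55. Of 13 immediate early genes, 11 were below 1 (median -0.29, percentile 0), with Nr4a1 at -0.89 and Jund at 0.43. CD40/NF-kB genes had a median of -0.16 (percentile 0), with Nfkbie at -0.36, Traf1 at -0.34 and Cd83 at 0.64. Their median was -0.08 with equal cluster shares and -0.09 with cells weighted alike. Cytokine receptors had a median of -0.17 (percentile 0), with Il6ra at -0.48 and Ifngr2 at 0.28. In the Day14 pair the medians were -0.06 for immediate early, 0.01 for CD40/NF-kB and -0.11 for cytokine receptor genes.

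Proliferation lists leaned the other way. All 18 G2/M genes were above 1 (median 0.14, percentile 100), with Ube2c and Aurka both at 0.25. Of 16 S phase genes, 14 were above 1 (median 0.10, percentile 99.4), with Rrm2 at 0.19. The 10 dark zone genes had a median of 0.08 (percentile 96.9, inside the random range), with Hmmr at 0.17 and Cxcr4 at -0.29. With equal cluster shares these 3 medians were 0.06, 0.06 and 0.00, at percentiles 97.52, 96.8 and 42.3, so that the S phase list was then also inside the random range. MYC-driven growth genes had a median of 0.10 (percentile 99.7), with Hspd1 at 0.20. GC identity genes had a median of -0.09 (percentile 0.01) and one of -0.14 with equal cluster shares, with Mef2b at -0.35. Light zone activation genes had a median of -0.12 (percentile 0.08) although the light zone marker Cd83 stood at 0.64 and Cd86 at 0.34, with Cd72 at -0.63. Medians in the Day14 pair were 0.07 for G2/M, 0.02 for S phase, 0.02 for dark zone and 0.06 for MYC-driven growth genes. They were 0.06 for GC identity and 0.07 for light zone activation genes.

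Of the other lists, MHC class II had a median of 0.08 (percentile 92.9, but 98.6 and above the random range with equal cluster shares), with H2-DMa at 0.36 and its regulator Ciita at 0.23. OXPHOS genes had a median of 0.06 (percentile 70.7), with Ndufa4 at 0.14. Glycolysis genes had a median of -0.06 (percentile 0.71), with Slc2a1 at -0.28, and apoptosis regulators one of -0.11 (percentile 0.40), with Bcl2 at -0.43 and Bbc3 at -0.36. Chaperones stood at 0.00 (percentile 28.5), with Hsp90aa1 at 0.14. Among markers of other cells, Lck was the 1 measured T cell gene (-0.46), 3 myeloid genes had a median of -0.23 (percentile 4.18; -0.06 with equal cluster shares) with Cd68 at -0.33, no stromal gene reached 5 CPM, and the 2 erythroid genes went both ways, Hbb-bt at -0.52 and Hbb-bs at 1.19. Sex-linked genes had a median of -0.04 (percentile 38.4), with Ddx3y at -0.06. Day14 pair medians were -0.06 for MHC class II, 0.00 for OXPHOS, 0.06 for glycolysis and 0.01 for apoptosis genes. For chaperones and myeloid genes they were 0.07 and -0.11. In all, 15 of the 22 lists with a random range lay outside it, which describes these 2 libraries and is not a test of the genotype.

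The same ratios were taken within classes. In memory-precursor-like cells Socs1 was at 33.7 CPM in the control and 119 CPM in the KO library (log2 1.82, interval 1.64 to 1.99), Il4i1 at 169 and 408 CPM (log2 1.27), and Klhdc2 at 23.1 and 196 CPM (log2 3.09). S100a10 was at 474 and 191 CPM (log2 -1.31) and Ccnd2 at 60.1 and 19.0 CPM (log2 -1.66) in the same class. The IL-4/STAT6 list had a median of 0.35 there, against 0.05 in light-zone-like and 0.12 in dark-zone-like cells. Fcer2a had a log2 ratio of 0.80 in light zone cells, 0.99 in dark zone cells and 0.54 in memory-precursor-like cells. The memory-like class had 85 genes past the size rule upward and 132 downward, and the light-zone-like class had 69 and 44. Plasma-like cells gave 318 and 55 genes, or 165 and 109 with TMM scaling. Differences between classes were not tested. The Day14 pair, for which the rule has 1 criterion fewer, gave 249 genes in memory-like, 27 in light-zone-like and 468 in plasma-like cells.

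Memory-precursor-like cells made up 16.2% of control cells (interval 15.4 to 17.0) and 12.9% of KO cells (interval 12.2 to 13.7). Plasma-like cells made up 3.58% (3.19 to 4.01) and 1.86% (1.56 to 2.20). Cells were clustered again without 1928 genes, which were the immunoglobulin genes and those that differed between the libraries. A gene differed with an absolute log2 ratio of at least 0.25 and an interval excluding equality. The memory-like class then held 8.81% and 5.88% and the plasma-like class 3.14% and 1.56%. A neighbouring unnamed cluster then held 8.20% and 7.68%, so that both together held 17.0% and 13.6%. The larger share was 1.26 times the smaller for memory-like cells in the chimaeras and 2.04 times between the Day14 libraries (5.87% and 2.88%). For plasma-like cells it was 1.93 times, against 1.26 times at day 14 (1.94% and 1.54%). Zone calls placed 52.5% of control and 58.8% of KO cells in the dark zone and 39.5% and 36.2% in the light zone. G2/M calls covered 26.7% and 31.2%. Light-zone-like cells made up 24.9% and 26.0%, dark-zone-like cells 24.3% and 26.7% and MYC-like cells 5.64% and 5.39%. The light-zone-like shares were 4.98% and 5.90% in cells above the median UMI count and 10.6% and 14.4% in a new clustering, so this class depended on depth and clustering.

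**Figure D2:**
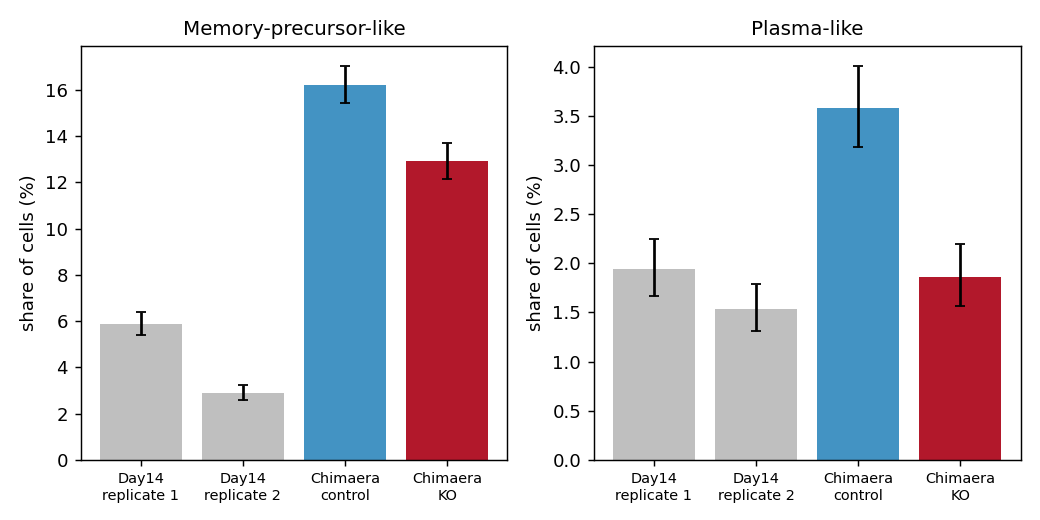
Share of cells (y axis, percent) in the memory-precursor-like and plasma-like clusters of each library, with 95% counting intervals. The memory-like share was 16.2% in the control and 12.9% in the KO library, and 5.87% and 2.88% in the Day14 libraries.

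Memory-precursor-like cells could be set against the other GC B cells of their library in 4 libraries, with 535, 307, 1304 and 945 memory-like cells. The class consists of clusters drawn on these same data, with G1 calls in 72.7% of its Day14 cells and 73.2% of its chimaera cells. The other cells include the dark-zone-like clusters, so lower cell division genes are partly built into the contrast. Libraries of a pair share 1 clustering, so signs that agree between them are not independent support. The GC programme of memory-like cells was lower in every library. All 15 GC identity genes were lower in 4 of 4 libraries, with a mean list difference of -0.91 log2 (SD 0.11, n = 4, exact sign-flip p = 0.125, the smallest possible). Rgs13 stood at -1.38, Gcsam at -1.40 and Bcl6 at -0.98. Cell division genes were lower too, G2/M by -1.13 (SD 0.11), S phase by -1.03 (SD 0.10) and dark zone by -1.03 (SD 0.10), with Cdk1 at -1.42. Naive follicular genes were higher by 1.82 (SD 0.83), 5 of 7 of them in every library, led by Ccr7 at 3.99 and Cd55 at 3.36. Interferon genes (0.69), MHC class II (0.63), cytokine receptors (0.67), CD40/NF-kB (0.22) and the 6 memory-associated genes outside the naming markers (0.44) had list means that were higher in 4 of 4 libraries, with Ifi203 at 3.53. Of those 6 genes, 3 were higher and 2 lower in every library. Apoptosis regulators (-0.32), MYC-driven growth (-0.29), glycolysis (-0.27), OXPHOS (-0.21) and chaperones (-0.48) had list means that were lower in 4 of 4.

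Trafficking receptors (0.74), light zone activation (0.14), the plasma list (0.09), immunoglobulin constant genes (0.52) and myeloid genes (1.43) had list means that were higher in 4 of 4 libraries. Of 11 immunoglobulin genes 3 were higher in every library, and of 3 myeloid genes Tyrobp (3.01) alone. Of the light zone genes 4 were higher and 4 lower in every library, and of the plasma genes 2 and 4. The IL-4/STAT6 list had a mean of 0.20 (SD 0.21, exact sign-flip p = 0.25) and was positive in 3 of 4 libraries, with the control at -0.08. Immediate early genes had a mean of 0.35 (SD 0.36, exact sign-flip p = 0.25) and were also positive in 3 of 4, with the KO library at -0.05. In all, 20 of 22 lists had 1 sign in every library, and none could pass a threshold of 0.05 with 4 libraries. Without naive follicular genes in any list, an alternative chosen after seeing the data, 19 of 21 lists had 1 sign, with means of 0.28 for trafficking, 0.35 for immunoglobulin and 0.13 for IL-4/STAT6 genes.

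The memory-like cells were deeper than the others, with median UMIs of 7850.5 against 6209 in the control. The alternative fixed beforehand thinned cells to 1000 UMIs and also took the UMI share of all list genes other than naming markers in place of the mean over the measured ones. It left 18 of 22 lists with 1 sign, with means of -0.01 for trafficking, -0.05 for light zone, -0.10 for plasma, 0.17 for immunoglobulin, 0.63 for myeloid, 1.02 for naive follicular (KO 0.15) and 0.07 for CD40/NF-kB genes (control -0.02). The IL-4/STAT6 (0.50) and immediate early lists (0.32) were then positive in 4 of 4. The IL-4/STAT6 list includes the MHC class II gene H2-Aa, and as a UMI share it followed the MHC class II list (mean 0.52). Each change was made alone after seeing the data. The share in all cells left 21 lists with 1 sign, with means of 0.11, 0.00, -0.13, 0.26, 0.64, 1.03 (KO 0.12) and 0.13 for the same 7 lists, and again had the IL-4/STAT6 (0.50) and immediate early lists (0.36) positive in 4 of 4. Thinned cells with the mean over genes left 16 lists with 1 sign, and these 7 means were 0.62, 0.10, 0.07, 0.44, 1.13, 1.77 and 0.19. The lists without 1 sign were IL-4/STAT6 (control -0.16), immediate early (control -0.02, KO -0.03), light zone (KO -0.04), plasma (control -0.10), memory-associated (control -0.02) and OXPHOS (0.10 and 0.07 in the Day14 libraries). Cells weighted alike left 19, without IL-4/STAT6, immediate early and OXPHOS.

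**Figure D3:**
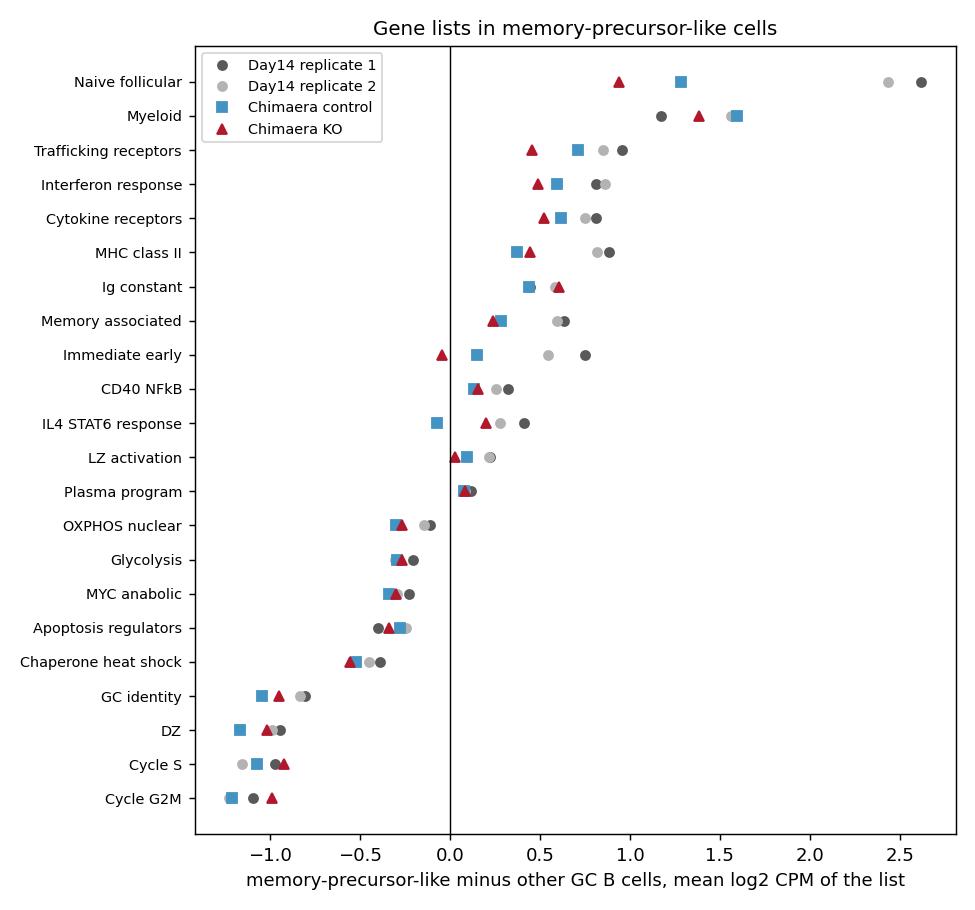
Mean difference in log2 CPM (x axis) between memory-precursor-like and other GC B cells for each gene list (y axis), 1 point per library. GC identity had a mean of -0.91 and naive follicular genes one of 1.82.

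Day 14 against day 7 asked how GC B cells differ between an early and an established response. Of 11995 tested genes, 4188 were higher and 3957 lower at day 14 (edgeR, adjusted p under 0.05). Adding the chimaera control, also from day 14, left 32 calls, with 2031 genes at an unadjusted p under 0.05. Restricting both days to a shared UMI window left 4421 calls, and 1330 of the original calls then had the opposite sign. That window, 7290 to 9998 UMIs, kept the 143 and 151 shallowest day 7 cells and the 979 and 1038 deepest day 14 cells. Day, gate, gene annotation, depth and cell filters changed together, so the values below describe the day 14 and day 7 tables. The control library lay on the day 14 side of day 7 for 54.7% of calls.

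Among lists, S phase genes fell in 14 of 16 members (14 adjusted over the list alone; camera adjusted p = 9.5e-05, and adjusted p = 0.706 with an estimated correlation). Rrm2 fell from 297 ± 1.82 to 96.0 ± 2.02 CPM (SD, n = 2 each; log2 -1.82, SE 0.06) and Dut had a log2 change of -1.22. In the shared UMI window both turned upward (0.65 and 0.51), as did the list (adjusted p = 0.00331). Phase calls went with depth. In Day7 replicate 1, G1 calls covered 26.7% of cells above the median UMI count and 47.5% of cells without doublets. For Day14 replicate 1 the values were 32.7% and 43.1%. Reversals in the window can therefore follow the cells it selects, and do not settle a direction. OXPHOS genes fell in 16 of 17 members (17 adjusted over the list alone; adjusted p = 1.99e-05, and adjusted p = 0.706 with an estimated correlation), with Ndufa4 at -1.94 and Uqcrb at -1.82. Glycolysis genes fell in 12 of 14 and rose in 1, Hk2 (14 adjusted over the list alone; adjusted p = 0.00618, and adjusted p = 0.706 with an estimated correlation), with Pgam1 at -2.04 and Aldoa at -1.64. Plasma cell genes fell in 12 of 14 and rose in 2 (14 adjusted over the list alone; adjusted p = 0.00199, and adjusted p = 0.706 with an estimated correlation). Jchain fell from 1972 ± 32.7 to 354 ± 10.3 CPM (SD, n = 2 each; log2 -2.67, SE 0.07), but stood at 1691 CPM in the chimaera control. Median log2 differences from day 7 were -0.82, -0.85, -0.98 and -1.44 for these 4 lists at day 14, and -0.27, 0.21, -0.13 and 0.14 in the control. In the shared UMI window the OXPHOS and glycolysis lists were no longer past the threshold (adjusted p = 0.36 and 0.215).

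The remaining lists did not pass camera. Their median and mean log2 differed in sign for light zone activation (-0.19 and 0.01), cytokine receptors (0.00 and -0.15) and chaperones (-0.15 and 0.13), all 3 downward in camera. G2/M genes fell in 11 members and rose in 5 (16 adjusted over the list alone), with Mki67 at 1.42, Cenpf at 1.05, Ccnb2 at -1.39 and Aurkb at -1.45 (adjusted p = 0.192, but 1.56e-06 upward in the UMI window). Dark zone genes fell in 5 and rose in 3 (8 adjusted over the list alone), with Gcsam at -1.37 and Hmmr at 0.58. Light zone activation genes fell in 7 and rose in 2 (9 adjusted over the list alone), with Bcl2a1d at -1.28 and Egr3 at 4.62. GC identity genes fell in 6 and rose in 4 (10 adjusted over the list alone), with Pou2af1 at -1.11 and Mybl1 at 1.11. IL-4/STAT6 genes fell in 10 and rose in 2 (12 adjusted over the list alone; adjusted p = 0.0861), with H2-Aa at -1.96, Socs3 at -1.68 and Bcl6 at 0.66. Il4ra did not pass (0.32, adjusted p = 0.1). MYC-driven growth genes fell in 12 and rose in 3 (15 adjusted over the list alone), with Ran at -1.74 and Nop56 at 0.59.

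Memory-associated genes rose in 7 and fell in 2 (7 adjusted over the list alone), with S1pr1 at 1.27. Naive follicular genes rose in 3 and fell in 2 (5 adjusted over the list alone), with Ccr7 at 2.34 and Vpreb3 at -1.50, and trafficking receptors rose in 7 and fell in 1 (8 adjusted over the list alone). Immediate early genes rose in 7 and fell in 2 (9 adjusted over the list alone). Fosb was at 0.70 ± 0.29 CPM at day 7, 33.7 ± 2.33 CPM at day 14 (SD, n = 2 each) and 1.17 CPM in the control. Fos was at 7.08, 84.3 and 9.67 CPM. CD40/NF-kB genes rose in 5 and fell in 5 (10 adjusted over the list alone), with Rel at 1.30 and Bcl2a1b at -1.08. MHC class II genes fell in 7 and rose in 1 (8 adjusted over the list alone), with H2-DMa at -1.20. Interferon genes fell in 6 (5 adjusted over the list alone), with Bst2 at -0.90 and Zbp1 at -0.87. Apoptosis regulators fell in 7 and rose in 3 (10 adjusted over the list alone), with Bak1 at -1.23 and Mcl1 at 0.996. Cytokine receptors fell in 7 and rose in 6 (13 adjusted over the list alone), with Il13ra1 at -4.04 and Tgfbr1 at 1.03. Chaperones fell in 3 and rose in 1 (4 adjusted over the list alone), with Hspa8 at -0.92.

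Markers of other cells also moved. Of 9 tested myeloid genes 3 rose and 2 fell (5 adjusted over the list alone). S100a9 had 2 counts at day 7 and 1393 at day 14, a ratio of 692 with a counting interval of 191 to 5719. Of 7 erythroid genes 5 fell (7 adjusted over the list alone), with Hba-a1 at 191 and 17.4 CPM in the day 7 libraries and 4.14 CPM at day 14. Of 4 T cell genes 2 fell (2 adjusted over the list alone), and of 3 stromal genes 2 rose and 1 fell (3 adjusted over the list alone). Xist, the sex-linked gene tested, was at 469 CPM at day 7, 1428 CPM at day 14 and 0.02 CPM in the control. Median mitochondrial shares were 2.67% and 2.64% at day 7, 7.69% and 8.11% at day 14, and 2.996% in the control.

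The 24 genes named by size were led by genes with almost no counts on 1 side. Ccnb1ip1 had 1 count at day 7 and 7923 at day 14, a ratio of 7871 with a counting interval of 1412 to 310942. Mia2 (chromosome 12, 59095799 to 59191583) had 1 and 5586 counts, a ratio of 5550 with an interval of 996 to 219236. Its neighbouring symbol Ctage5, singled out after the values were seen, was listed in the Day7 table alone, with 1181 and 3238 counts. Atp5o had no count at day 14, at least 8945-fold lower against a floor of 3 counts over the group, and Nupl1 and Ints5 were at least 748-fold and 732-fold lower. Srp54a rose (8.97 log2) where Srp54b fell (-5.67), a pair of near neighbours on chromosome 12 (55080262 to 55115367 and 55155104 to 55189573). The other genes that rose were Platr25 (7.49), Fosb (5.58), Atrip (4.94), Hist1h2br (4.30), Gxylt2 (3.58), Ppp6r2 (3.49), Fos (3.38), Zfp445 (3.34) and Csf2rb (3.17). The others that fell were Hgs (-4.90), Hba-a1 (-4.80), Slpi (-3.85), Gclm (-3.81), Prg2 (-3.71), Eno1b (-3.29), Tgtp1 (-3.20) and Tonsl (-3.16). Of the 24, 10 share same-strand exon sequence with another gene model, against 8.97% of tested genes (two-sided Fisher's exact p = 1.97e-05).

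Across genes, the day 14 to day 7 ratio rose with transcript length (Spearman rho 0.351 over 11884 genes, which are not independent replicates), while rho was -0.112 for the control to day 7 ratio. Among the 2377 shortest genes the median log2 ratio was -0.37 at day 14 and 29.3% of calls were upward. Among the 2377 longest the median was 0.59 and 86.9% were upward.

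**Figure D4:**
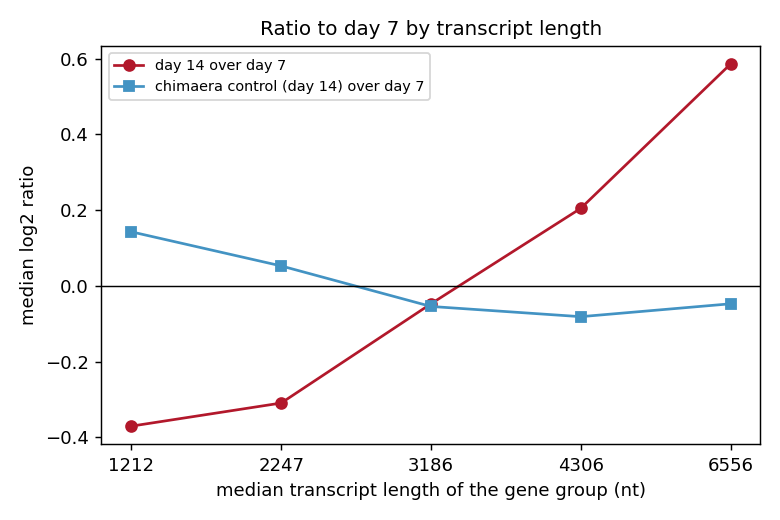
Median log2 ratio to day 7 (y axis) in 5 groups of genes ranked by transcript length (x axis, nucleotides), for the Day14 libraries and for the chimaera control. The Day14 medians ran from -0.37 to 0.59.

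Shares of cells at the 2 days rest on different gates. Dark zone calls covered 55.1% and 58.1% of day 7 cells and 60.5% and 60.8% of day 14 cells. MYC-like cells made up 12.9% and 21.4% at day 7 against 5.73% and 6.48% at day 14, and plasma-like cells 4.84% and 3.99% against 1.94% and 1.54%. The day 14 plasma-like class joined a cluster with weaker plasma markers (1.15% and 0.873%) to a stronger one (0.79% and 0.667%). Among cells above the median UMI count of the shallower library of each day, dark zone calls covered 71.1% and 69.1% at day 7 and 68.6% and 70.9% at day 14, a choice made after seeing the data. An exact permutation test of 2 against 2 cannot go below 0.333. No day 7 cluster could be named memory-precursor-like. An unnamed day 7 cluster of 632 cells did reach a median log2 ratio of 1.59 over the memory-precursor markers. The naming rule left it out because haemoglobin genes led it while it kept B cell transcripts. Memory-like cells at day 7 are therefore neither shown nor excluded.

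Immunoglobulin genes were listed for the day 14 and chimaera libraries. Ighm took most heavy-chain constant UMIs, 68.6% and 67.0% at day 14, 55.4% in the control (interval 55.2 to 55.7) and 62.5% in the KO library (62.2 to 62.8). Ighg1 took 11.5% and 6.90% at day 14, and 22.2% and 22.1% in the control and KO libraries. Without plasma-like cells the latter were 18.3% and 20.4%. Ighg2c took 6.08% in the control and 2.79% in the KO library, but also differed between the Day14 libraries (2.97% and 9.66%). Igha took 4.51% and 1.90% (2.77% and 0.71% without plasma-like cells). Ighe took 0.222% and 0.792%, which became 0.269% and 0.292% without plasma-like cells. In CPM, the immunoglobulin constant list had a median log2 KO to control ratio of -0.49, with 11 of 12 genes below 1, Igha at -1.72 and Ighe at 1.37. Between the Day14 libraries the median of this list was -0.24. Lambda light chains took 22.7% and 18.8% of light-chain constant UMIs at day 14 and 47.3% and 49.8% in the control and KO libraries. Ighv1-72, the segment known from NP-binding antibodies, was the most used heavy-chain V segment in 3 of 4 libraries, with 16.1% and 8.30% of Ighv UMIs at day 14, 13.04% in the control and 14.1% in the KO library.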

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

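All tests of explanations below, with their cut-offs, were chosen after the results were seen. The settings for scaling, cluster shares, cell depth and thinning combined with list shares had been fixed beforehand, but only as alternatives.

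In Day14 replicate 2, 3.01% of cells (321 of 10648) formed a deposited cluster that held 0 of 9109 cells of replicate 1, with an exact 95% upper limit of 0.04% there. This signal lay outside the comparisons of the report. In these cells, Igkv6-23 took 71.6% of Igkv UMIs, against 1.83% and 6.23% in the other cells of the 2 libraries, Ighv1-26 took 60.9% of Ighv UMIs, and Ighg2c took 74.97% of heavy-chain constant UMIs. Why replicate 1 lacked these cells was not tested.

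In memory-precursor-like cells, the IL-4/STAT6 list difference was -0.08 in the chimaera control and positive in both Day14 libraries (0.41 and 0.28). The immediate early list difference was -0.05 in the KO library and positive in both Day14 libraries (0.75 and 0.54). The libraries moved in opposite directions, and neither difference was tested. Taken as the list's share of UMIs, both lists were positive in all 4 libraries, with cells thinned to 1000 UMIs (0.22 in the control and 0.21 in the KO library) and with all cells (0.26 and 0.11). In thinned memory-like cells of the control, the IL-4/STAT6 list took 3.49% of UMIs and the MHC class II list 3.66%. The control difference was 0.24 for MHC class II, so the positive IL-4/STAT6 share is not separate from MHC class II genes. With the mean over genes, thinned cells still gave -0.16 in the control and -0.03 in the KO library. The negative signs therefore depend on how a list is summarised and not on depth alone.

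Fcer2a, Il4i1 and Socs1, targets of IL-4 signalling in B cells, had higher values in the KO library. With the clusters given equal shares the lowest of their log2 ratios was 0.58, which argues against cluster shares as the cause, and over 3 other scalings the lowest was 0.51, which argues against scaling. With 1 library per group, a difference that any 2 libraries may show cannot be told apart from host genotype: the 2 Day14 libraries differed in 19 genes on the first criteria and the chimaeras in 80, but that is 1 pair against 1.

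Memory-precursor-like and plasma-like shares were smaller in the KO library. Clustering without the genes that differ between the libraries left 5.88% against 8.81% memory-like cells, which argues against a clustering drawn on those genes, and among deep cells the shares were 16.8% against 19.5%, which argues against depth. For memory-like cells, library-to-library spread could account for the whole difference: the Day14 shares differed 2.04 times and the chimaera shares 1.26 times. For plasma-like cells the Day14 shares differed 1.26 times and the chimaera shares 1.93 times, and 1 pair cannot tell host genotype apart from spread. A biological effect of the host stroma stays open for both.

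Day 14 and day 7 differed in 8145 genes. The control library, made at day 14 with the same gate as the Day14 libraries, lay on the day 14 side in 54.7% of calls, close to an even split, so much of the difference may follow the table or library set and not the day. A transcript length trend is not the whole cause, since 6158 calls kept their call and sign once it was removed. For the 24 genes named by size, annotation that differs between the tables is a candidate explanation. Ctage5 was listed at day 7 alone, where its neighbour Mia2 had 1 and 0 counts, and Srp54c was listed everywhere except day 7. Of the 24, 10 share exon sequence with another gene model. Overlap within 1 annotation does not show a difference between the tables, and Mia2, Srp54a and Srp54b have no such overlap. Irradiation and marrow transfer also set the control apart from the Day14 libraries, as did sex-linked expression, depth and cell filters. Median UMIs per cell were 6676 in the control against 3399 and 3178.5 at day 14. Mitochondrial counts reached at most 9.97% in the chimaera cells and 19.99% in the Day14 cells. A difference between days therefore stays open.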

How the results depend on the processing

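Alternatives on mitochondrial limit, UMI window, transcript length, clustering without differing genes, lists with the control added, day shares in deep cells, memory lists without naive genes and thinning apart from list shares were chosen after seeing the data. KO against control gave 9 and 4 genes at a log2 of 1, 55 and 128 at 5 CPM, and 24 lower genes with equal cluster shares, all set by the rule's own construction except the last. Memory-like shares were 19.5% and 16.8% in deep cells, 9.27% for KO in a new clustering, and 8.81% and 5.88% without differing genes. Plasma-like shares were 5.85% and 2.63%, then 3.13% and 1.56%. Deep cells gave dark zone shares of 71.1% and 69.1% at day 7 and 68.6% and 70.9% at day 14, so the days overlapped, and MYC-like shares of 15.4% against 7.42% and 8.73% (23.9% in the other day 7 library). Plasma-like cells gave 165 and 109 genes with TMM. Day calls fell to 32 with the control and 4421 in the UMI window. They ranged from 6312 to 8874 leaving out 1 library, where a lone library is assumed to vary like the others. A replicate block gave 8401 calls and 6 lists, and deviations of same-numbered libraries correlated at 0.179 across genes. Lists past the threshold numbered 0 with an estimated correlation, 11 with fry, 9 in the UMI window, 10 with the control and 6 without any 1 library, against 4. In the UMI window Rrm2 (0.65), Dut (0.51), Aurkb (0.37) and Il4ra (-0.69) reversed, and Il4ra also without the length trend (-0.06). Lists that reversed in the UMI window, with adjusted p, were dark zone 0.703, S phase 0.00331, G2/M 1.56e-06, memory-associated 0.703, naive follicular 0.848, MYC-driven growth 0.0239, trafficking 0.796 and chaperones 0.138. CD40/NF-kB genes reversed without the length trend (0.864) and with the control (0.9), and cytokine receptors with the mitochondrial limit (0.832), with the control (0.456) and without Day7 replicate 1 (0.752). Cytokine receptor values leaving out 1 library ranged from 0.752 to 0.854 and those of myeloid genes from 0.122 to 0.826, the latter reversed without Day7 replicate 2. As shares of UMIs in thinned cells, memory-like light zone (-0.05), plasma (-0.10) and trafficking (-0.01) lists reversed. Shares in all cells reversed light zone and plasma (-0.13), and thinned cells with the mean over genes reversed none, so the list summary moved the first 2 and trafficking turned only with both changes. Ighg1 by cells was 13.8% and 8.15% at day 14, 24.1% in the control and 25.3% in the KO library. As a share of UMIs without plasma-like cells, Ighg1 was at 18.3% in the control and 20.4% in the KO library. The cause was not tested for any of these. Leaving immunoglobulin genes out of the day comparison was not run, since no shared symbol is one. Among named genes, 749 values on day 14 against day 7 and 308 on KO against control kept their direction and side or stayed within their error, while 66 on the days were weaker and 52 on KO against control moved. Depth limits the day 7 comparison in the UMI window to 143 and 151 cells, the shallowest of day 7, set against the deepest of day 14.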

Other observations

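The outcomes below were chosen after their values were seen. Nfil3, a transcription factor of the IL-4/STAT6 list, lay below the CPM limit of the size rule, at 2.28 CPM in the control and 7.46 CPM in the KO library (log2 1.71, interval 1.43 to 1.99). In memory-precursor-like cells its log2 ratio was 4.09 (interval 3.28 to 5.03), from 13 and 177 UMIs. Ccr7 had a ratio of -1.93 on the log2 scale and the Day14 pair one of -1.60, so that a somewhat smaller value in the same direction also arose between libraries of 1 group. Socs1 stood higher in memory-like than in other cells of the KO library (0.94) and lower in the control (-0.51), and Il4i1 stood at 1.44 and 0.44. These contrasts were not tested.

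Chimaera libraries had Ddx3y at 31.4 and 30.1 CPM, while the Day7 and Day14 libraries had 0 counts of it, and Xist was at 0.02 CPM or below in the chimaeras. Sex-linked expression thus differed between the chimaeras and the other 4 libraries, which the labels do not mention. A day 7 cluster of 632 cells was led by haemoglobin genes, Lyz2 and Klf2 and kept B cell transcripts, and took 28.5% and 13.6% of the cells of the day 7 libraries. Its median log2 ratio over the memory-precursor markers was 1.59. Ighv3-6 took 23.3% of Ighv UMIs in Day14 replicate 2, where it ranked above Ighv1-72.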
